A study of Homo sapiens with 8 samples.

How the data were processed

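Human bone marrow stromal cells from 4 donors, numbered 1 to 4 here, were grown to passage 3 to 4 and kept for 24 h either untreated or with 10 ng/ml fibroblast growth factor 2 (FGF2), per the labels. Each donor gave 1 untreated and 1 FGF2 culture, so there were 8 libraries. Per the labels' protocols, messenger RNA was captured on oligo(dT) beads from RNA with an integrity number above 8, fragmented, copied with random primers and sequenced as single reads of 50 bases on 2 lanes, a protocol that does not mark strand. Which library ran on which lane, the aligner, the counting program, the annotation and the genome build are not given in the sources used here. The labels' extraction text also mentions array hybridization, but the values have the steps of sequencing reads.

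The deposited table holds a signal per gene, which is the gene's read count divided by 1 size factor per library and rounded to 1 decimal by the authors, as judged from the values. Within each column every value lay within 0.06 of a whole multiple of 1 step, so whole reads were recovered for 100.0% of values. The recovered depth was 19875198 to 20687381 reads in the untreated libraries and 20385282 to 23654876 in the 4 FGF2 libraries, and a gene at the minimum mean of 10 rests on few reads. The table lists 60107 genes by Ensembl identifier, of which 56531 (94.1%) were given a symbol from reference tables. It has 1 further line without an identifier, which was left out, and 0 columns of values were left unmapped.

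The values in donor 1's FGF2 column were not on the lines of their genes. Spearman's rho across 13795 genes between this column and each of the other 7 was 0.12, against 0.973 to 0.994 among those 7 (genes are not independent replicates, and no p is given). A monotone alignment to the mean of the other libraries placed values for 59063 genes and left 1044 genes without one, and the order of the 543 values before and the 501 after the ordered stretch was not recovered. The design fixed before the data were examined took all 8 libraries. Because of the misplaced column the comparison was made on 7 libraries, 4 untreated and 3 with FGF2, which hold 3 complete donor pairs. The 8 columns as deposited, and the 8 libraries with the aligned column, were run as alternatives chosen after seeing the data.

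FGF2 and untreated libraries were compared with limma 3.58.1 in R 4.3.3, with a mean trend in the variances, on log2(value + 1) for genes with a mean of at least 10 over the 7 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over 14040 genes. Fold changes are on this log2(value + 1) scale, which understates the change of genes with few reads. The fit had no donor term (5 residual degrees of freedom). The donors are shared between the groups, so a fit with the donor as a block, called the paired fit (2 residual degrees of freedom, with a prior worth 10.5), is printed beside a result where it changes the call or moves a count by more than 1.5-fold. As a check of the pairing, the deviations of same-donor libraries from their group means correlated at 0.69, 0.62 and 0.54 for donors 2, 3 and 4, across genes, and each of these libraries correlated best with its own donor's partner. FUT8 alone was also tested with an exact permutation test of the 35 splits of 7 libraries and an exact sign-flip test of the donor differences, both two-sided.

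Before the data were examined, 26 gene lists were written. Each was tested against all other tested genes with camera, two-sided, with a preset inter-gene correlation of 0.01 and with an estimated correlation. Each was also tested with fry, which does not set a list against other genes. It asks whether the genes of a list move on balance one way or, in its mixed form, in either direction. The list p-values were adjusted over the 26 lists. Members called are counted after adjustment over all genes and after adjustment over the list alone. A further list of amino acid response genes was written after values had been seen. The genes named in the text follow a rule fixed before the data were examined: the 12 largest rises and 12 largest falls among genes called, with a mean of at least 50, named and protein coding, and changed in 1 direction in every donor pair. To these were added FUT8, each called member of the fucosylation and integrin lists, and up to 4 members of each other list with the smallest adjusted p. The rule was written for 4 donors and 8 libraries, and because of the misplaced column it was applied to 3 donor pairs and 7 libraries. In all, 130 genes were named by this rule, while 32 higher and 12 lower calls without a name or not protein coding were only counted. Of the named genes, 3 are not reported here. Where few members of a list were called, members outside the rule were named as well (such as EGR1, FGF5, FBN2, VCAM1, LAPTM5 and PECAM1), chosen after their values were seen. Of the 130 genes, 2 share more than 20% of their exonic bases with another tested gene in GENCODE 29. These are CD68 (81.7%, with a transcript on the same strand) and FGF14 (31.6%, with ITGBL1 on the opposite strand). Their values are uncertain, that of FGF14 because the reads carry no strand. For CD68 strand would not separate the overlapping transcript either.

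The alternatives fixed before the data were examined were the donor block, median-ratio rescaling, quantile normalization, both the block and rescaling, pseudocounts of 0.1 and 5, no filter and a mean of at least 50, limma without the trend and with robust variances, a 2-fold threshold, and each donor and each library left out in turn. Added after seeing the data were edgeR 4.0.16 quasi-likelihood tests and DESeq2 1.42.0 on the recovered reads, each without and with the block, the 8-library fits, and the paired fit without each of donors 2, 3 and 4. The tests across genes were tested on simulated data in which 200 genes were changed, all drawn from genes with a mean of at least 50 reads. Changes in genes with means from 10 to 50 were not simulated. With limma and no donor term on 13905 simulated genes, 20.9% of 1.5-fold changes, 76.1% of 2-fold changes and 92.4% of 3-fold changes were called, with 0 false calls among 126. In the paired fit these shares were 91.0%, 100.0% and 100.0%, with 8 false calls among 202. The simulated changes were the same in every donor and touched far fewer genes than the paired fit called in the data. The simulated rates need not hold for the paired calls in the data.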

Results

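RNA sequencing was used to compare bone marrow stromal cells, plastic-adherent cells of the marrow that can form bone, fat and cartilage, after 24 h without or with 10 ng/ml FGF2. FGF2 is a growth factor that signals through receptor tyrosine kinases and the ERK pathway. The series title concerns migration under FGF2 and core fucose on the N-glycans of integrins. Values are the authors' scaled read counts, given as mean ± SD over 4 untreated and 3 FGF2 libraries with 19875198 to 23654876 reads each. Log2 folds (FGF2 over untreated) carry their SE, and adjusted p-values come from limma.

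With FGF2, 25 of 28 DNA replication genes, 29 of 30 mitosis genes and 8 of 20 ERK target genes were called higher (1 ERK target lower), and FGFR2 and 9 of 29 fibrillar matrix genes lower. Of 14040 genes tested, 718 were higher and 219 lower with FGF2, of which 70 and 66 changed at least 2-fold. The paired fit called 3221 higher and 1458 lower, among them all 937 genes called without the donor term. A list's paired count has to be read against those 4679 of 14040 genes. The share called higher was 76.6%, and 58.6% after median-ratio rescaling. In the paired fit the share was 68.8%, and 51.9% after rescaling. These counts depended on single libraries. Removing donor 1's untreated library gave 1079 higher and 359 lower, and removing the untreated library of donor 2, 3 or 4 gave 199 and 63, 213 and 63, or 147 and 53. Removing the FGF2 library of donor 2, 3 or 4 gave 435 and 160, 27 and 10, or 133 and 41. Without donor 2 the counts were 5 and 3, without donor 4 they were 0 and 1 (2061 genes at an unadjusted p under 0.05), and without donor 3 limma called 0 (1827 at an unadjusted p under 0.05). In the paired fit, 3795 and 2040 genes were called without donor 2, 1689 and 776 without donor 3, and 2654 and 1179 without donor 4. These fits hold fewer donor pairs and fewer residual degrees of freedom than the full paired fit, and their variances rest mostly on the prior across genes. The larger count without donor 2 is therefore not stronger evidence.

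Of the 130 genes named by rule, 73 were called without the donor term and 119 in the paired fit. All 73 kept their direction when any donor or library was removed, but between 0 (without donor 3) and 70 (without donor 1's untreated library) kept their call. These genes were called on the same libraries that the reduced fits reuse, so the kept direction is little further evidence. Among the 119, 119, 101 and 111 kept their call in the paired fit without donors 2, 3 and 4. The p-values of those fits rest little on the spread between donor pairs, so calls kept there are weak evidence. These limits apply to each gene below that was called.

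The largest rise among the named genes was that of ESM1 (ENSG00000164283), which encodes a secreted proteoglycan of activated endothelium. It went from 781 ± 165 to 6694 ± 1874, a log2 fold of 3.09 ± 0.23 (adjusted p = 0.00422), with 1 untreated library, that of donor 3, at 535.6 against 843.5 to 889.9 in the others. THBD, the thrombin receptor thrombomodulin, rose from 29.2 ± 5.10 to 162 ± 39.5 (2.42 ± 0.22, adjusted p = 0.00617). PREX1, an exchange factor for Rac, rose by 2.09 ± 0.42 (adjusted p = 0.0300), and DUSP4, a phosphatase that inactivates ERK, by 2.16 ± 0.40 (adjusted p = 0.0243). Among the 12 largest rises were also CFAP91, INSC, ABTB3, GNGT1, COL17A1, PTPN22 and FAM107B, with log2 folds from 1.78 (FAM107B) to 2.61 (CFAP91). Each of these 11 was higher with FGF2 in 3 of 3 donor pairs, which the naming rule requires, so the agreement is no further evidence.

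Without the donor term SAMD11 fell most among the genes named by rule, from 803 ± 139 to 144 ± 48.5, a log2 fold of -2.52 ± 0.25 (adjusted p = 0.00642). In the paired fit TMEM119 (-2.64) and FGFR2 (-2.53) fell slightly more than SAMD11 (-2.52). FGFR2, a receptor for fibroblast growth factors, fell from 312 ± 88.2 to 62.1 ± 15.1 (-2.28 ± 0.28, adjusted p = 0.00882), with donor 1's untreated library at 180.9 against 342.8 to 367.5 in the others. TMEM119, a membrane protein of osteoblasts, fell by 2.43 ± 0.49 on the log2 scale (adjusted p = 0.0302), and DACT1, a regulator of Wnt signalling, fell by 2.02 ± 0.30 (adjusted p = 0.0126). FOS, an immediate early transcription factor, fell by 2.08 ± 0.42 (adjusted p = 0.0293). The other 7 of the 12 largest falls were NDNF, CYP1B1, LBH, CEMIP, SYTL2, CRISPLD2 and DUSP2, with log2 folds from -2.51 (NDNF) to -1.68 (DUSP2). By the same rule each of the 12 was lower in 3 of 3 donor pairs.

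**Figure D1:**
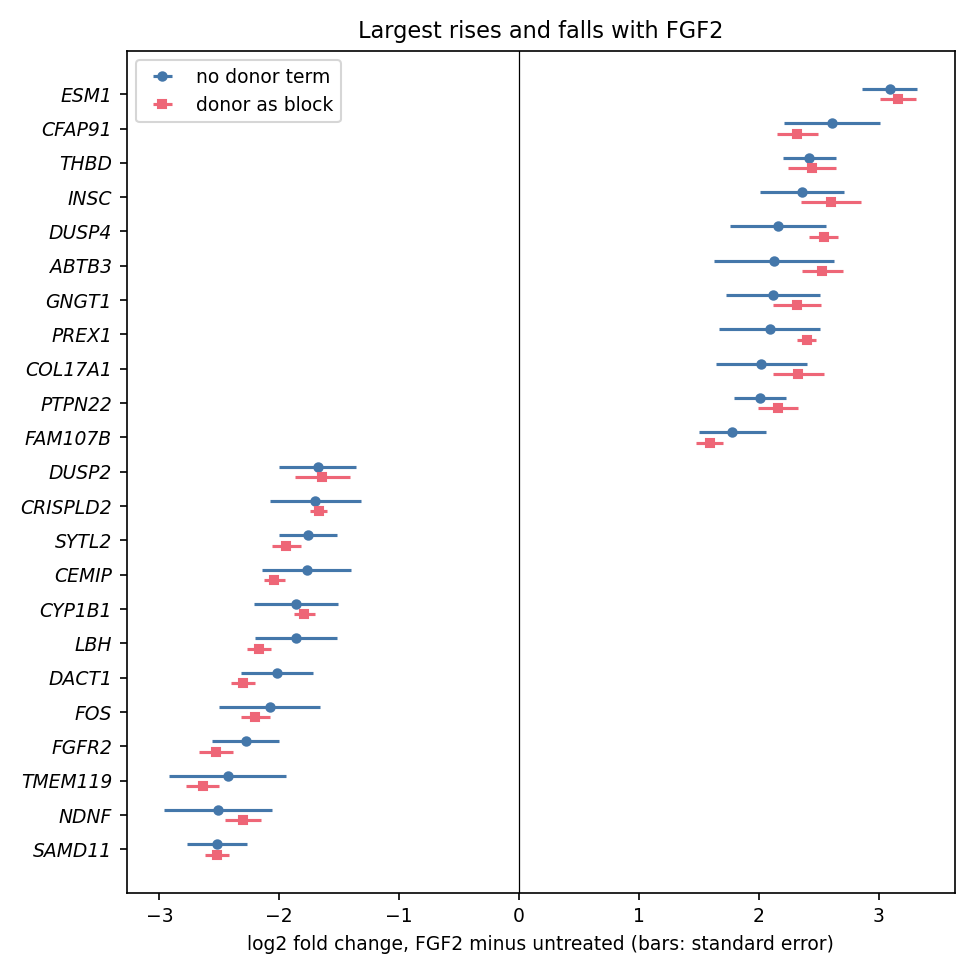
Log2 fold (FGF2 over untreated, x axis) with its standard error for 11 of the 12 largest rises and the 12 largest falls, from the fit without the donor term and the paired fit. Without the donor term ESM1 has the largest rise at 3.09 and SAMD11 the largest fall at -2.52. Each of the 23 genes has the same direction in both fits, which follows from the rule that chose them.

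FUT8 (ENSG00000033170), the only enzyme that adds core fucose to N-glycans, was measured at 1431 ± 384 in untreated and 2347 ± 481 in FGF2 libraries. Its log2 fold of 0.73 ± 0.22 did not pass without the donor term (adjusted p = 0.0983, exact permutation p = 0.0857 over 35 splits). With pairing FUT8 rose by 0.88 ± 0.06 (adjusted p = 7.1e-07), with differences of 0.83, 0.97 and 0.83 in donors 2, 3 and 4. The exact sign-flip p was 0.25, the smallest that 3 pairs can give. Without donor 1's untreated library the unpaired call passed (0.88, adjusted p = 0.0332). Of 13 fucosylation genes tested, covering GDP-fucose synthesis, transport and fucosyltransferases, 0 were called by limma without the donor term, also 0 adjusted over the list alone. With pairing 1 gene was called higher (FUT8) and 2 lower, SLC35C2 (-0.24 ± 0.08, adjusted p = 0.0326) and POFUT2, which adds O-fucose (-0.26 ± 0.06, adjusted p = 0.00540). Adjusted over the list alone the numbers were the same. SLC35C2 lost its call in the paired fit without donor 3 (adjusted p = 0.239) or donor 4 (0.162), and POFUT2 without donor 3 (0.126). The list did not pass camera (adjusted p = 0.164, and 0.340 paired) or fry (0.643, and 0.662 paired), though it passed fry's mixed form (0.0113, and 0.0111 paired), which takes rises and falls together.

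Among 39 genes of N-glycan assembly and processing, B4GALT1, a galactosyltransferase, fell by 0.52 ± 0.07 on the log2 scale (adjusted p = 0.0115) and the other 38 did not pass. Adjusted over the list alone, 1 fell as well. With pairing 7 were called higher and 3 lower (B4GALT1, MAN1B1 and DDOST), 4 and 4 after rescaling, and 6 and 2 adjusted over the list alone. Of all 14040 genes the paired fit called 4679, a larger share than in this list or the fucosylation list. Higher in the paired fit were MGAT5, which starts a branch of complex N-glycans (0.68 ± 0.07, adjusted p = 1.9e-05), the mannosidase MAN2A1 (0.51 ± 0.07, adjusted p = 1.2e-04) and the sialyltransferase ST3GAL3 (0.39 ± 0.08, adjusted p = 0.00190). ST3GAL3 was not called by DESeq2 with the donor block (adjusted p = 0.0604). The list did not pass camera (adjusted p = 0.156, and 0.749 paired), but passed fry in the paired fit (0.0460, against 0.850 unpaired).

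Integrin subunits, the cell's receptors for matrix, moved in both directions. ITGA6, a laminin receptor subunit, rose from 641 ± 124 to 1814 ± 420 (1.5 ± 0.19, adjusted p = 0.00899). The collagen receptor subunit ITGA11 fell from 11498 ± 1533 to 5994 ± 1694 (-0.97 ± 0.18, adjusted p = 0.0253), ITGA7 fell by 0.77 ± 0.15 (adjusted p = 0.0262), the fibronectin receptor subunit ITGA5 fell by 0.36 ± 0.08 (adjusted p = 0.0431) and ITGB8 fell by 1.06 ± 0.25 (adjusted p = 0.0485). Thus 1 of 19 tested subunits rose and 4 fell, and 1 and 5 adjusted over the list alone. With pairing 4 rose and 6 fell (5 and 6 adjusted over the list alone). ITGA2, another collagen receptor subunit, was added there with the largest rise, 2.80 ± 0.14 (adjusted p = 3.6e-08, and 0.179 unpaired). ITGA3 (0.25 ± 0.06) and ITGA4 (0.46 ± 0.09) also rose, while ITGAV (-0.47 ± 0.08) and ITGA8 (-1.23 ± 0.31) fell. ITGA8 had few reads, 23.2 ± 16.7 untreated and 11.7 ± 5.56 with FGF2. Without donor 3, ITGA3 (adjusted p = 0.0957) and ITGA4 (0.0630) lost their paired calls, and ITGA8 lost it without donor 4 (0.0717). With the donor block ITGA3 was not called by edgeR (adjusted p = 0.0645) or DESeq2 (0.0904), nor ITGA8 by DESeq2 (0.0630). The list median was -0.01, its mean 0.02 and its camera direction down, short of the threshold (adjusted p = 0.164, and 0.335 paired), as was fry (0.454, and 0.941 paired) except in its mixed form (1.5e-04, and 0.0104 paired).

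**Figure D2:**
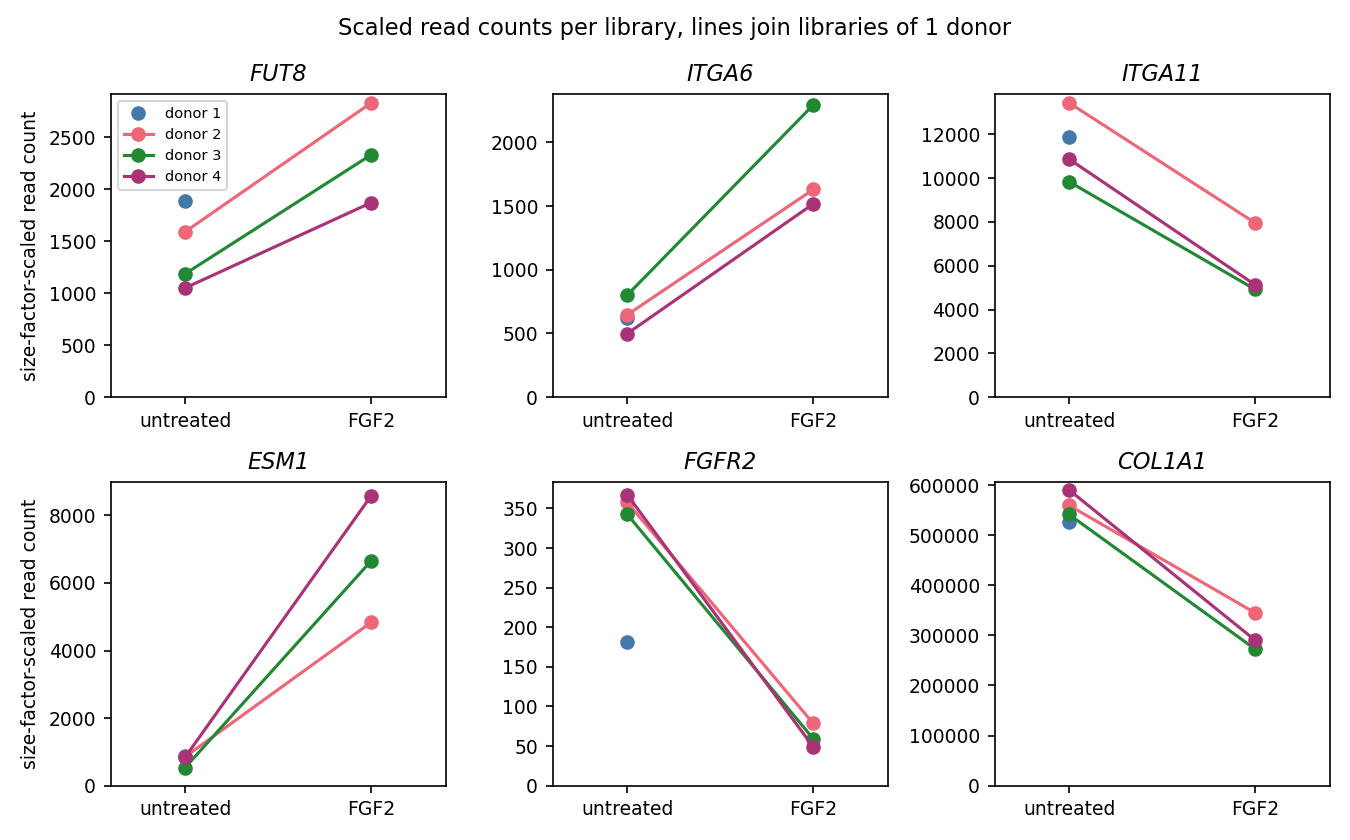
Scaled read counts (y axes, from 0) of FUT8, ITGA6, ITGA11, ESM1, FGFR2 and COL1A1 in each untreated and FGF2 library, with lines joining the libraries of 1 donor. FUT8 is higher with FGF2 in each of donors 2, 3 and 4, by 0.83, 0.97 and 0.83 on the log2 scale, and donor 1 has an untreated value only.

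Of 30 genes of focal adhesions and integrin signalling, PAK1, a kinase activated by Rac and CDC42, rose (0.54 ± 0.10, adjusted p = 0.0261) and the other 29 did not pass, with 1 higher and 0 lower adjusted over the list alone. The paired fit called 4 higher and 10 lower (6 and 11 adjusted over the list alone). PXN (0.49 ± 0.06, adjusted p = 5.9e-05), PTK2, the focal adhesion kinase (0.39 ± 0.06, adjusted p = 3.9e-04) and CRKL (0.23 ± 0.06, adjusted p = 0.0119) rose there. CRKL lost its call after rescaling (adjusted p = 0.0802) and without donor 3 (0.202). The list moved down in the paired fit (camera adjusted p = 0.0380, and 0.328 with an estimated correlation) and did not pass without it (0.433).

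Among receptors that guide migration PLXNA2, a semaphorin co-receptor, rose from 1148 ± 156 to 3014 ± 277 (1.4 ± 0.11, adjusted p = 0.00445) and EPHB2, an ephrin receptor, rose by 0.57 ± 0.07 (adjusted p = 0.00907). PDGFRB, a receptor for platelet-derived growth factor, fell by 0.87 ± 0.12 (adjusted p = 0.00942). Of 20 tested, 2 rose and 1 fell (6 and 2 adjusted over the list alone), and 14 rose and 3 fell (PDGFRB, NRP2 and UNC5B) in the paired fit, where HMMR was added (0.64 ± 0.09, adjusted p = 1.9e-04). The list passed upward (camera adjusted p = 0.0497, and 0.589 with an estimated correlation). That call ended without FGF2 replicate 2 (adjusted p = 0.444), without donor 2 (0.345), 3 (0.0618) or 4 (0.0586), and without the untreated library of donor 3 (0.120) or 4 (0.138).

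Among 22 matrix proteases and their inhibitors, PLAU, the urokinase that activates plasminogen, rose from 286 ± 96.5 to 648 ± 75.0 (1.22 ± 0.22, adjusted p = 0.0234), and ADAMTS2, which trims procollagen, fell by 0.77 ± 0.15 (adjusted p = 0.0262). The counts adjusted over the list alone were also 1 and 1. Pairing gave 10 that rose and 3 that fell. The urokinase receptor PLAUR rose (0.98 ± 0.06, adjusted p = 1.4e-07), and MMP2 fell beside ADAMTS2 and ADAM12 (-0.65 ± 0.06, adjusted p = 8.4e-06). The list median was -0.05 and the mean 0.23, and camera gave a downward direction unpaired (adjusted p = 0.394) and an upward one paired (0.185), where fry passed it (0.0333, against 0.937 unpaired).

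Of 20 ERK target genes 8 rose and 1 fell (12 and 2 adjusted over the list alone), and 16 rose and 2 fell in the paired fit. SPRY2, a feedback inhibitor of the pathway, went from 594 ± 108 to 1646 ± 105 (1.49 ± 0.15, adjusted p = 0.00617), the cyclin CCND1 from 13233 ± 1741 to 26205 ± 2294 (0.99 ± 0.12, adjusted p = 0.00882), and the transcription factors FOSL1 and ETV4 rose by 1.07 ± 0.14 and 1.4 ± 0.22 (adjusted p = 0.00924 and 0.0153). The 1 that fell was the immediate early factor EGR1 (-1.12 ± 0.25, adjusted p = 0.0398), joined in the paired fit by IER3 (-0.42 ± 0.07, adjusted p = 3.6e-04). The list passed (camera adjusted p = 1.7e-04, and 0.354 with an estimated correlation).

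Among 13 FGF receptors and heparan sulphate co-receptors FGFR2 was the 1 called, also adjusted over the list alone. The list passed camera downward (adjusted p = 0.0181, and 0.269 with an estimated correlation) but not fry (0.121), nor camera without donor 2's FGF2 library (0.0597). In the paired fit 1 rose (the syndecan SDC1, 0.52 ± 0.06, adjusted p = 5.8e-05) and 5 fell, FGFR2, the syndecans SDC2 and SDC4 and the glypicans GPC1 (-0.42 ± 0.06, adjusted p = 3.2e-04) and GPC4 (-1.0 ± 0.09, adjusted p = 3.5e-06). Of 6 FGF ligand genes limma called 0, also adjusted over the list alone. The cells' own FGF2 transcript fell in the paired fit by 0.70 ± 0.09 (adjusted p = 7.1e-05), FGF7 fell by 1.27 ± 0.13 (adjusted p = 9.3e-06) and FGF5 rose by 0.31 ± 0.09 (adjusted p = 0.0185, but 0.0777 after rescaling). FGF14, whose exons overlap another gene, had a paired log2 fold of 0.33 ± 0.19 (adjusted p = 0.195). The ligand list did not pass camera (adjusted p = 0.394, and 0.335 paired), but passed fry in the paired fit (0.0460, against 0.785 unpaired).

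Proliferation genes rose nearly without exception over the 7 libraries. Of 28 DNA replication genes 25 rose and 0 fell (28 adjusted over the list alone, and 28 in the paired fit), and of 30 mitosis genes 29 rose and 0 fell (30 and 30). The replication factor CDC45 went from 516 ± 31.7 to 871 ± 2.31 (0.76 ± 0.07, adjusted p = 0.00617), the transcription factor E2F1 rose by 0.91 ± 0.09 (adjusted p = 0.00617), the mitotic kinase AURKA by 0.64 ± 0.07 (adjusted p = 0.00705) and PLK1 by 0.56 ± 0.07 (adjusted p = 0.00882). Both lists passed (camera adjusted p = 6.3e-22 and 7.7e-22, and 0.175 and 0.109 with an estimated correlation). Of their named members only E2F1 and HMMR have a value in donor 1's FGF2 column put back in gene order. Donor 1's log2 differences were 0.16 and -0.15, against paired log2 folds of 0.94 and 0.64. In the paired fit of 8 libraries both were still called higher (limma adjusted p = 0.00336 and 0.0441). Among 30 ribosome biogenesis genes UTP4 (0.31 ± 0.07, adjusted p = 0.0378) and NOP58 (0.29 ± 0.07, adjusted p = 0.050, just under the threshold) were the 2 called, both higher, against 17 adjusted over the list alone, 24 in the paired fit and 19 in the paired fit after rescaling. That list passed upward (camera adjusted p = 9.9e-07, and 0.354 with an estimated correlation). Of 6 replication histone genes tested, H2AC6 fell (-0.75 ± 0.16, adjusted p = 0.0378), also adjusted over the list alone, and the list passed downward (camera adjusted p = 0.00630, and 0.264 with an estimated correlation), but not without donor 4 (0.0566) or its FGF2 library (0.0536), or in the paired fit after rescaling (0.0732). Histone genes are near copies of each other and most of their transcripts lack a poly(A) tail, so these values are uncertain.

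Among 29 genes of the fibrillar matrix 0 rose and 9 fell (12 adjusted over the list alone). COL1A1, the most abundant collagen chain in these cells, went from 554024 ± 27795 to 302342 ± 37722 (-0.88 ± 0.17, adjusted p = 0.0286), COL1A2 fell by 0.92 ± 0.14 (adjusted p = 0.0162), COL12A1 by 1.55 ± 0.26 (adjusted p = 0.0192) and COL5A1 by 0.70 ± 0.10 (adjusted p = 0.0105). In the paired fit 1 rose, the fibrillin FBN2 (0.31 ± 0.07, adjusted p = 0.00608), and 19 fell. The list passed downward (camera adjusted p = 7.8e-11, and 0.109 with an estimated correlation). The 10 most abundant genes took 12.9% to 15.7% of the reads in untreated and 10.3% to 10.8% in the 3 FGF2 libraries.

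Among 20 contractile and myofibroblast genes 2 fell, TGFBI (-0.76 ± 0.13, adjusted p = 0.0204) and the tropomyosin TPM1 (-0.66 ± 0.15, adjusted p = 0.0454), and 1 rose, smoothelin, SMTN (0.69 ± 0.09, adjusted p = 0.00899). The counts adjusted over the list alone did not differ, and 1 rose and 16 fell in the paired fit, where THBS1 fell by 1.04 ± 0.09 (adjusted p = 5.2e-06). The list passed camera downward (adjusted p = 4.6e-05, and 0.354 with an estimated correlation) but not fry without the donor term (0.268, and 0.0333 paired).

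Lineage markers were mixed. Of 14 osteoblast genes 3 fell and 0 rose (5 and 1 adjusted over the list alone): the matrix protein SPARC (-0.75 ± 0.14, adjusted p = 0.0251), COL1A1, and the transcription factor DLX5 (-0.93 ± 0.20, adjusted p = 0.0348). Pairing gave 4 higher, SPP1 (adjusted p = 0.0395, but 0.0707 after rescaling), BMP2 and PHEX among them, and 6 lower. The osteoblast list passed downward (camera adjusted p = 0.0198, and 0.354 with an estimated correlation) with a median of 0.00 and a mean of -0.07, but not after rescaling (0.0662), without the untreated library of donor 2 (0.105) or without the FGF2 library of donor 3 (0.0646). Of 10 chondrocyte genes HAPLN1 fell (-0.93 ± 0.21, adjusted p = 0.0415). Adjusted over the list alone 2 fell, and in the paired fit 1 rose, SOX9 (1.87 ± 0.37, adjusted p = 0.00177), and 5 fell, HAPLN1, ACAN, COMP, SOX6 and COL11A1 (-1.77 ± 0.10 for COL11A1, adjusted p = 1.0e-07). SOX9 had few reads, 14.5 ± 10.6 untreated and 37.0 ± 17.4 with FGF2. The chondrocyte list passed downward (camera adjusted p = 0.0133, and 0.175 with an estimated correlation). Of 8 adipocyte genes FABP5, a fatty acid binding protein with few reads, rose from 8.33 ± 2.88 to 24.2 ± 6.46 (adjusted p = 0.0476), with 1 higher and 3 lower adjusted over the list alone. With pairing 2 were higher, FABP5 (adjusted p = 0.00951, but 0.122 without donor 3 and 0.140 by DESeq2) and PLIN2, and 3 lower, CEBPD (-1.86 ± 0.12, adjusted p = 2.7e-07), CEBPB (-0.40 ± 0.08, adjusted p = 0.00257, but 0.120 over 8 libraries with donor 1's FGF2 column put back in gene order) and ZNF423 (-0.43 ± 0.10, adjusted p = 0.00471, and 0.0621 without donor 3). The adipocyte list did not pass camera (adjusted p = 0.182, and 0.232 paired) or fry (0.454, and 0.279 paired).

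Among 18 stromal surface markers NT5E, which encodes CD73, rose from 14290 ± 2027 to 25105 ± 2529 (0.82 ± 0.13, adjusted p = 0.0163) and PDGFRB fell, also adjusted over the list alone, while the paired fit called 5 higher and 5 lower. Higher there were NT5E, CD9, ANPEP, CD44 (0.56 ± 0.07, adjusted p = 1.1e-04) and PDGFRA (0.46 ± 0.08, adjusted p = 5.3e-04), and lower were PDGFRB, THY1, MCAM, LEPR and VCAM1 (-2.32 ± 0.19 for VCAM1, adjusted p = 2.7e-06). The list did not pass camera (adjusted p = 0.725, and 0.681 paired) but passed fry in the paired fit (0.0343, against 0.454 unpaired), with a median of 0.04, a mean of -0.01 and a downward test. Of 6 blood cell and macrophage markers limma called 0 unpaired, also adjusted over the list alone, and 1 higher in the paired fit, LAPTM5 (0.69 ± 0.19, adjusted p = 0.0146; list camera adjusted p = 0.395, and 0.872 paired). CSF1R stood at 141 ± 74.1 and 109 ± 37.4 (adjusted p = 0.674), and CD68, whose exons overlap another gene, at 233 ± 22.0 and 251 ± 16.6 (adjusted p = 0.60). Of 7 endothelial markers tested 0 were called unpaired, also adjusted over the list alone, and 4 were higher in the paired fit (3 after rescaling), PECAM1, CDH5, ROBO4 and TEK. TEK, an angiopoietin receptor, went from 283 ± 77.0 to 410 ± 158 (paired log2 fold 0.49 ± 0.09, adjusted p = 0.00130). CDH5 was at 11.2 ± 5.09 and 25.8 ± 14.1, and its paired call (adjusted p = 0.0235) ended without donor 3 (0.208) or 4 (0.0715). ROBO4 (paired adjusted p = 0.0224) lost its call without donor 4 (0.180). The endothelial list did not pass camera (adjusted p = 0.310, and 0.186 paired) or, unpaired, fry (0.0666), but passed fry in the paired fit (0.0405).

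Of 23 cytokine and chemokine genes HBEGF, a ligand of the EGF receptor, rose from 1123 ± 273 to 2239 ± 158 (1.02 ± 0.17, adjusted p = 0.0176), also adjusted over the list alone. With pairing 12 were higher and 2 lower (CXCL12 and CSF1), with IL11 (0.81 ± 0.08, adjusted p = 1.1e-05), CXCL3 (2.41 ± 0.30, adjusted p = 5.5e-05) and CXCL2 (1.60 ± 0.32, adjusted p = 0.00213) higher. The list did not pass camera (adjusted p = 0.855, and 0.139 paired) or fry (0.607, and 0.0937 paired).

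Of 22 cholesterol synthesis genes 3 fell, SQLE (-0.45 ± 0.06, adjusted p = 0.0110), HMGCS1 (-0.63 ± 0.11, adjusted p = 0.0187) and MSMO1 (-0.48 ± 0.10, adjusted p = 0.0288). Adjusted over the list alone 1 rose and 3 fell, and in the paired fit EBP rose (0.29 ± 0.07, adjusted p = 0.00478, and 0.0695 without donor 3) and 10 fell (list camera adjusted p = 6.7e-04, and 0.175 with an estimated correlation). Of 19 interferon response genes XAF1 (-1.0 ± 0.21, adjusted p = 0.0345) and BST2 (-1.38 ± 0.33, adjusted p = 0.0484) fell, also adjusted over the list alone, and the paired fit called 1 higher (IFI44, adjusted p = 0.0268, but 0.0937 after rescaling) and 9 lower, including MX2 (-2.27 ± 0.31, adjusted p = 1.3e-04). MX2 had few reads, 45.5 ± 30.6 untreated and 7.0 ± 6.17 with FGF2. With donor 1's FGF2 column put back in gene order, its log2 difference in donor 1 was -0.24. The interferon list passed downward (camera adjusted p = 4.4e-04, and 0.354 with an estimated correlation). Of 20 immediate early and stress genes 4 fell and 0 rose (8 and 1 adjusted over the list alone): FOS, CHAC1 (-1.24 ± 0.14, adjusted p = 0.00755), asparagine synthetase, ASNS (-0.78 ± 0.10, adjusted p = 0.00907) and the chaperone HSPA5 (-0.41 ± 0.10, adjusted p = 0.0496). Pairing gave 3 higher (JUN, HSPH1 and HSPA8) and 12 lower, and the list passed downward (camera adjusted p = 4.5e-05, and 0.109 with an estimated correlation). Of 13 mitochondrially encoded genes limma called 0 unpaired, also adjusted over the list alone, 5 higher in the paired fit (MT-ND2, MT-ND3, MT-CO3, MT-ATP6 and MT-CYB) and 0 in the paired fit after rescaling. MT-CO3 had a paired log2 fold of 0.28 ± 0.10 (adjusted p = 0.0471, and 0.151 after rescaling, 0.285 without donor 3 and 0.246 without donor 4). The mitochondrial list passed upward in the paired fit (camera adjusted p = 0.0332, and 0.688 with an estimated correlation). Unpaired it did not pass (0.0637), but it did without donor 1's untreated library (0.0263), without donor 2 (6.5e-05) and without donor 2's untreated (0.0393) or FGF2 library (1.4e-04), and its direction was down without donor 4 (0.981).

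**Figure D3:**
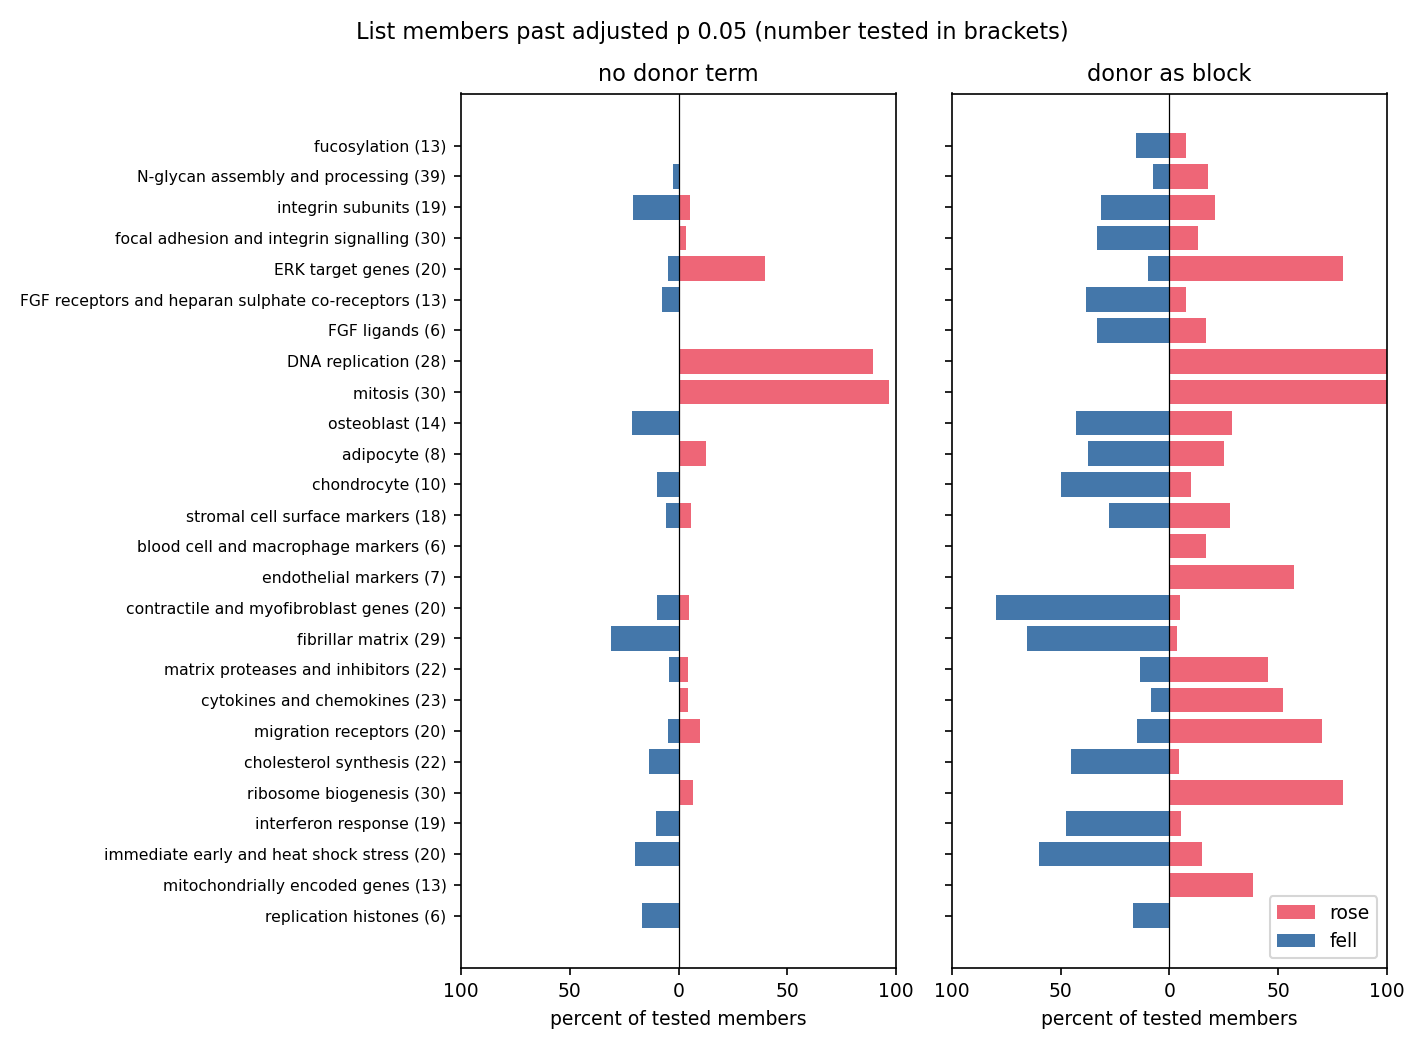
Percent of tested members of each gene list that rose or fell with FGF2 (x axis), without the donor term and in the paired fit. DNA replication (25 of 28 higher) and mitosis (29 of 30 higher) stand apart upward without the donor term, where 9 of 29 fibrillar matrix genes are lower. With pairing 16 of 20 contractile genes and 19 of 29 fibrillar matrix genes are lower.

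Without the donor term, 14 of the 26 lists passed camera with its preset correlation and 16 in the paired fit. With an estimated correlation limma's camera passed 0 lists in either fit (6 unpaired and 2 paired lists at an unadjusted p under 0.05), and fry passed 7 unpaired and 17 paired. Unpaired, fry did not pass the migration receptor (0.121), FGF receptor (0.121), contractile (0.268), osteoblast (0.148), cholesterol (0.0666), interferon (0.315) and replication histone (0.0666) lists, which camera did. In its mixed form fry passed 18 and 23. Fry does not set a list against other genes, and the paired fit called 4679 of 14040 genes, so many lists can pass it.

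Donors also set libraries apart. The first principal component of the 7 libraries held 37.1% of the variance and set donors 1 and 2 (-38.98 to -24.59) apart from donors 3 and 4 (17.29 to 31.67). The second held 25.2% and separated the treatments, with untreated libraries at 11.88 to 26.06 and FGF2 libraries at -33.65 to -22.39.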

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

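The comparison of the skipped genes with libraries of 1 treatment was planned before its result was seen, while putting donor 1's FGF2 column back in order was chosen after seeing the data. Chance sets apart about 1 in 20 groups of 4. Here 11 of 130 groups of 4 untreated libraries, 1 group per named gene, held a library whose gap to its nearest neighbour, as a share of the group's range, exceeded Dixon's critical value at 95%.

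In donor 1's untreated library FGFR2 stood at 180.9 (others 342.8 to 367.5), SLC35C2 at 1050.2 (985.7 to 987.9), MGAT5 at 3862.6 (2300.0 to 2441.4), ZNF423 at 542.6 (294.2 to 318.3), CSF1R at 251.8 (95.4 to 113.2), THBS1 at 98468.1 (181260.9 to 191011.0) and PLAU at 429.5 (221.1 to 248.7). In donor 3's untreated library ESM1 stood at 535.6 (843.5 to 889.9), FOS at 1336.9 (451.9 to 566.2) and CRKL at 1714.2 (1813.7 to 1821.5). COL12A1 stood at 16710.8 in donor 2's untreated library (11205.0 to 12022.6).

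In donor 1's FGF2 column, which the comparison does not use, FUT8 had a value of 3147.5 once the column was put back in gene order, above the 1051.3 to 1892.8 of the untreated libraries. Donor 1's difference in FUT8 was then 0.73 on the log2 scale, and over 4 pairs the mean was 0.84 ± 0.10 (SD) with an exact sign-flip p of 0.13, the smallest that 4 pairs can give. Of 3720 placed genes called in the paired fit of donors 2 to 4, 3097 (83.3%) moved in the same direction in donor 1, and 343 of 377 (91.0%) among those changed at least 2-fold.

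The genes that the ordered stretch of this column skips responded to FGF2 far more often than the rest: 959 of 1037 tested (92.5%) were called in the paired fit, 822 higher and 137 lower, against 3720 of 13003 placed genes (28.6%). The skipped genes also made up 608 of the 937 calls without the donor term. If the alignment skipped genes because they differ from its reference, a reference of the 3 FGF2 libraries alone would remove the excess, but 91.8% of the genes skipped against that reference were called. Higher read counts do not account for it either, since placed genes weighted to the same means were called in 34.9% of cases. A candidate explanation left open is that the lines before and after the stretch were ordered by a measure of the response to FGF2 when the table was made. Several orders by such measures were tried outside the tests given here and none matched the values, so their order was not recovered.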

How the results depend on the processing

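The tests on recovered reads, the 8-library fits and the paired fit without single donors were chosen after seeing the data. The donor block gave 3221 genes higher and 1458 lower, 2194 and 2036 with rescaling, against 718 and 219. Without the block, 402 were higher and 284 lower after median-ratio rescaling, 365 and 261 after quantile normalization and 389 and 288 by edgeR. Limma without the trend gave 328 and 119, and DESeq2 gave 857 and 666. The 2-fold threshold left 70 and 66. With the block, edgeR gave 2133 and 2245 and DESeq2 1411 and 1247. With the column put back in gene order limma called 0 and 0 of 13012 genes (2299 at an unadjusted p under 0.05). With the block it called 1890 and 1040. That column has no placed value for 608 of the 937 genes called over 7 libraries without the block, so these were not tested. Of the 329 that were tested, 0 kept their call without the block and 314 with it. With the 8 columns as deposited limma called 0 and 0 (107 at an unadjusted p under 0.05). Leaving out donors or libraries gave 0 to 1079 higher and 0 to 359 lower, and 1689 to 3795 and 776 to 2040 in the paired fit. FUT8 passed with the block (0.88), the block with rescaling (0.80), DESeq2 (0.65), edgeR and DESeq2 with the block (0.79 and 0.80) and the 8-library block (0.84). Leaving out donors or libraries without the block gave 0.59 to 0.88, passing there only without donor 1's untreated library. With the block FUT8 passed without donor 2, 3 or 4 (adjusted p = 5.6e-33, 1.5e-06 and 1.7e-21). Those fits hold fewer donor pairs and fewer residual degrees of freedom than the full paired fit, which has 2 and a prior worth 10.5. Their p-values rest mostly on the prior across genes and little on the spread between donor pairs. A smaller adjusted p there is therefore not stronger evidence. Over all settings the adjusted p ran from 5.6e-33 to 0.589. The number of lists passing was 12 to 17 in other settings of camera, 0 with an estimated correlation and 7 by fry. Camera has no robust form, so that setting was not run. The migration receptor list also lost its call with a pseudocount of 5 (0.0505), a mean of at least 50 (0.112) and no trend (0.0676), and the osteoblast and chondrocyte lists lost theirs after quantile normalization (0.218 and 0.0655). The mitochondrial list passed after quantile normalization (0.00165), without a filter (0.00699), with the block and rescaling (0.0279) and in the 8-library fit without the block (0.0329, and 0.0830 with it). With a mean of at least 50 the adipocyte list passed (0.0476), and in the 8-library fit without the block the integrin (0.0458) and focal adhesion (0.0465) lists did. The 8-library fits leave out genes without a placed value, among them ITGA2, ITGA6, PAK1 and CRKL, which rose in the paired fit. These lists therefore had other members there than over 7 libraries. Of the other 129 named genes, CSF1R and FCER1G, neither called, changed sign. CSF1R moved to 0.00 with the block and to 0.06 in both 8-library fits, and ranged from -0.63 to 0.00 when libraries were left out. FCER1G moved to 0.09 in both 8-library fits, and ranged from -0.34 to 0.13. The paired fit added calls for 45 of the 129 and removed 0, and it also added calls for FUT8 and, by camera, the focal adhesion and mitochondrial lists. Of the 119 named genes called with the block, 114 kept their call after rescaling, 113 by edgeR and 102 by DESeq2 with the block, and 60 of the 67 with a placed value in donor 1's FGF2 column did so in the 8-library block fit. By fry the block took the lists passing from 7 to 17, and from 18 to 23 in the mixed form. Fewer libraries leave fewer degrees of freedom, and for the other differences the cause was not tested. At this depth and size 20.9% of simulated 1.5-fold changes, all in genes with a mean of at least 50 reads, were recovered without the donor term. A missing call without the donor term therefore does not show that a gene stayed level.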

Other observations

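The amino acid list, the genes named in the next 2 paragraphs, the marker sums for endothelial cells and the test of the authors' scaling were chosen after the results were seen. The test of abundant genes and the counts of other splits were not.

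Of 28 genes induced by amino acid shortage through the transcription factor ATF4, 11 fell and 0 rose with FGF2, and in the paired fit 24 fell and 2 rose (ATF5 and SLC7A1), but after rescaling 25 fell and 0 rose (adjusted p = 0.0700 for ATF5 and 0.0720 for SLC7A1). DDIT4, an inhibitor of mTORC1 signalling, fell by 1.59 ± 0.31 on the log2 scale (limma adjusted p = 0.0279), ADM2 fell by 1.12 ± 0.11 (adjusted p = 0.00617), and PSAT1, an enzyme of serine synthesis, fell by 0.65 ± 0.08 (adjusted p = 0.00899). ATF4 itself had a log2 fold of -0.26 ± 0.08 (adjusted p = 0.102, and 0.00665 paired). Adjusted together with the 26 fixed lists, the list had a camera adjusted p of 6.2e-19, and an adjusted p of 0.0846 with an estimated correlation. It was written after ASNS and CHAC1 had been seen to fall, and 6 of its members belong to lists fixed beforehand, so its p-values are not independent evidence.

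Beside ESM1 and THBD, 4 other genes with known roles in endothelium were called higher, picked by hand and not tested as a group. The fixed endothelial list did not pass camera (adjusted p = 0.310, and 0.186 paired) but passed fry in the paired fit (0.0405, against 0.0666 unpaired). PODXL, a sialomucin, went from 10457 ± 1644 to 29448 ± 6585 (1.48 ± 0.18, adjusted p = 0.00882), and TM4SF1 from 3834 ± 131 to 8871 ± 697 (1.21 ± 0.07, adjusted p = 0.00274). APLN, the ligand apelin, rose by 1.63 ± 0.26 (adjusted p = 0.0176), and TFPI, an inhibitor of coagulation, by 1.58 ± 0.27 (adjusted p = 0.0189).

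Endothelial cells in the FGF2 cultures would bring their abundant transcripts along. The 12 endothelial markers fixed beforehand, VWF, PECAM1 and CLDN5 among them, rose together by 3.48% of the rise of ESM1, most of it TEK (2.15%). That sum argues against such cells as the source of ESM1's rise. It was 155% of the rise of THBD, but 127.1 of the summed rise of 206.0 was that of TEK, already at 282.6 in untreated cells. Markers with few reads moved apart: VWF went from 6.35 to 4.80, CLDN5 (1.0 and 0.97) and TIE1 (1.5 and 1.53) hardly moved and KDR was listed at 0 in both groups, but PECAM1 went from 8.35 to 19.6, CDH5 from 11.15 to 25.83 and ESAM from 4.05 to 11.73. Endothelial cells therefore stay open for THBD, and a few of them are not excluded. A response of the stromal cells themselves may remain as a hypothesis for ESM1, found and tested on the same data.

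More genes were called higher than lower, 68.8% of calls in the paired fit. After median-ratio rescaling the share was 51.9%, but rescaling centres the folds whatever their cause, so whether the authors' scaling between libraries was the cause stays open. The 50 most abundant genes took 23.0% to 26.0% of the summed values in untreated and 20.6% or less in FGF2 libraries. Scaling on the sum without them moved the median log2 fold of all genes from 0.07 to 0.00 and the share to 53.1%. The excess of rises may therefore come from fewer reads of abundant genes under a scaling near the total. This scaling also evens out the sum of the remaining genes whatever the cause of their change. A true rise of most transcripts per cell stays open and was not tested.

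Over all 35 splits of the 7 libraries chance can be excluded for the count without the donor term only if the libraries are interchangeable, and they are not, since the deviations of same-donor libraries correlated at 0.69, 0.62 and 0.54. The real split called 937 genes, the only 1 with as many. The highest other called 282 and set the libraries of donors 1 and 2 against those of donors 3 and 4. Of the 8 splits that part all 3 donor pairs the highest other called 207, and 8 splits are too few for a share under 0.05. The split with 207 is the treatment contrast reversed, with donor 1's untreated library moved to the FGF2 side, so 207 is not a chance level. In the paired fit the real labels called 4679 genes and the highest other of the 4 exchanges within donors called 0, with the real one the only 1 as large, but 4 splits are too few for a share under 0.05.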
